A study of Caenorhabditis elegans with 8 samples.

How the data were processed

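RNA of dissected Caenorhabditis elegans gonads was measured by RNA sequencing in 3 genotypes. These were the wild type (wt), the sin-3(syb2172) mutant and the hda-3(ok1991) mutant. SIN-3 is the scaffold of a conserved co-repressor complex that carries histone deacetylases, and HDA-3 is a class I histone deacetylase. Per the labels' protocols, gonads of young adults were dissected in cold water without an anaesthetic, RNA was reverse-transcribed and amplified by a Smart-seq2 type method, and libraries were made with the SMART-Seq v4 and Nextera XT kits and sequenced as single reads of 50 bases. The labels call the replicates independent biological replicates and state 3 per strain. The libraries analysed here are wt replicates 3, 4 and 5, sin-3 replicates 3, 4 and 5, and hda-3 replicates 4 and 5, which makes 8 libraries in 3 groups.

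The deposited count files hold whole-number read counts per gene, 1 file per library, not normalised by the authors. Per the submitters' processing notes, fastp 0.20.1, STAR 2.7.3a, HTSeq 0.7.2 and DESeq2 1.36.0 were used; their roles and settings, the genome build, the annotation and the strand setting of the counting are not given in the sources used here. Of the 46934 gene identifiers in the files, 46923 were in the WBcel235 annotation of Ensembl release 115, and 44112 had a symbol in the gene name table. Only 24 reads lay on identifiers outside that annotation. Coordinates and chromosomes are those of WBcel235. The files also hold counter lines that name no gene, and these were kept out of library sizes and tests. Reads on no feature were 1.06 to 2.27% of a library's total, ambiguous reads 0.673 to 1.55%, and reads aligned to more than 1 place 3.03 to 5.57%. Because such reads were not counted per gene, counts of near-identical copies, such as the genes for major sperm proteins, histones and the small nspd, nsph and ssp families, are uncertain. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart, and 34 of the 120 named genes have a span that overlaps another coding gene, sin-3 among them.

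The authors also deposited 2 tables of their own comparisons, each mutant against wt, with a log2 fold change and its standard error, an unadjusted p-value and an adjusted p-value per gene from DESeq2, per the file headers. The mean counts in these deposited tables equalled those recomputed from the deposited counts for all 13084 genes listed for sin-3 and all 12398 listed for hda-3, within a tolerance of 1e-06. These tables were used only for a comparison of calls.

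Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, robust fit, TMM factors) on the counts as deposited. All 8 libraries entered 1 model with a term for each genotype, so that the groups shared 1 estimate of the spread. Genes were kept by edgeR's filterByExpr, with a minimum count of 10 and a minimum total of 15, which left 10302 genes. P-values were adjusted by Benjamini and Hochberg, and a gene was called at an adjusted p under 0.05. Adjusted p-values of single genes in the text are from this test. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of the F statistic. CPM is the usual scaled count on TMM-normalised library sizes, which include reads on ribosomal RNA genes. Values are given as mean ± SD. Counts for all 8 libraries were simulated from the wt means, with 200 genes changed by known folds. Fewer genes passed the filter there, so the rates do not describe genes that rise from near 0 in wt. Each gene was drawn independently, without the shifts common to many genes by which the real replicates differed. The share of false calls in these sets is therefore not that of the real calls. In these sets the sin-3 step (8259 genes) recovered 88.9% of 4-fold rises and 31.2% of 2-fold rises. It recovered 82.6% of falls to 0.25 and 21.3% of falls to 0.5, and 5.5% of its calls were false. The hda-3 step (8309 genes) recovered 76.6%, 14.0%, 79.6% and 19.1%, with 2.17% of calls false.

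Gene lists were fixed before the data were examined, as were the model, the threshold and the rule for named genes. There were 23 lists: SIN3 and histone deacetylase genes, spermatogenesis, major sperm proteins, oogenesis, germline stem cells and mitotic zone, meiosis, germ granule and small RNA, chromatin repressors and histone methylation, dosage compensation, sex determination, histones, cell cycle and DNA replication, apoptosis and DNA damage, heat shock and stress, nuclear-encoded respiratory chain, mitochondrially encoded, cytosolic ribosomal proteins, and markers of intestine, muscle, neuron, epidermis and cuticle, and somatic gonad, and transcription factors of embryonic and neuronal fates. Each list was tested with camera (limma 3.58.1, preset correlation 0.01, log2 CPM with a prior count of 2), with Benjamini-Hochberg adjustment over the lists of a comparison, and again with the correlation estimated per list and with fry. fry asks whether a list's genes move, on balance, one way and does not compare them with other genes. The same camera test compared X-linked with other nuclear genes, and the size of that difference is the median log2 fold change of X-linked genes minus that of autosomal genes. The text names sin-3 and hda-3; for each comparison with wt, the 10 genes with the largest rise and the 10 with the largest fall among called genes of at least 10 CPM on average whose mutant libraries all lay on one side of all wt libraries; 5 and 5 such genes between the mutants; up to 4 called members per list by smallest adjusted p, or the 1 member closest to the threshold where none passed; and the 5 X-linked genes with the largest rise. Genes outside this rule are said to have been chosen after their values were seen.

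Values of whole libraries were compared by exact permutation tests, two-sided (scipy 1.17.1), 14 tests in all; the smallest p they can give is 0.1 for 3 against 3 libraries and 0.2 for 2 against 3. Ratios of counts for genes with 1 to 3 counts in a group have 95% exact intervals on pooled counts, and a group at 0 was set to a floor of 3 counts over the group. These cover counting error only, since amplified reads without molecular identifiers are not independent molecules. No pair of replicates agreed within sampling noise: chi-square per degree of freedom was 31.4 to 330 within groups. To give the overlap and covariance of the comparisons with no effect, 20 sets of unchanged groups were simulated against the same wt libraries. Alternatives were other scalings (RLE factors; TMM on autosomal genes), no filter or a stricter filter on low counts, DESeq2 1.42.0, limma voom with sample quality weights, a model of only the groups compared, the replicate number as a block, a 2-fold minimum, restricted gene sets for the X comparison, and leaving out each library in turn. Where this left 1 hda-3 library, that library was assumed to vary like the other groups. Counts without ribosomal RNA genes, autosomal genes matched to X-linked genes, and the covariance and correlation over the genes of the simulated sets, were added after the data were seen.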

Results

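The study measured gene expression in the germ line of young adult hermaphrodites of 3 genotypes, and asked how loss of SIN-3 or of HDA-3 alters the germline transcriptome. There were 3 wt, 3 sin-3 and 2 hda-3 libraries. Reads counted on genes numbered 21607989, 16979891 and 23535429 in wt replicates 3, 4 and 5, 24389531, 21499389 and 22807971 in sin-3 replicates 3, 4 and 5, and 23927346 and 14550417 in hda-3 replicates 4 and 5. Nuclear ribosomal RNA took 63.2, 64.001 and 47.7% of these reads in wt, 79.0, 58.2 and 41.8% in sin-3 and 50.9 and 48.2% in hda-3. Reads on other genes ranged from 5110133 in sin-3 replicate 3 to 13268274 in sin-3 replicate 5. The TMM factors spanned a wide range, from 0.424 in sin-3 replicate 3 to 2.297 in sin-3 replicate 5, with 0.547, 0.631 and 0.960 in wt and 1.62 and 1.60 in hda-3. Replicates of 1 group therefore differed in composition, and the 3 sin-3 libraries did so most.

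The mutated genes were examined first. The gene sin-3 (WBGene00004117; chromosome I, 8416816 to 8425051, WBcel235) was at 55.1 ± 3.34 CPM in wt (SD, n = 3) and at 57.6 ± 0.576 CPM in hda-3 (n = 2). In the sin-3 libraries it had 0, 2 and 1 reads, against 606, 616 and 1274 in wt, a level 1630 times lower on pooled counts (95% interval 557.1 to 7909). The gene hda-3 (WBGene00001836; chromosome I, 11912793 to 11917712) was at 31.9 ± 6.21 CPM in wt and 16.3 ± 3.40 CPM in hda-3, a log2 fold change of -0.98 (SE 0.25, edgeR adjusted p = 0.0178). Every hda-3 library lay below every wt library. That call was lost without hda-3 replicate 4 (-0.76, adjusted p = 0.264), without wt replicate 5 (-0.81, adjusted p = 0.0654) and without sin-3 replicate 4 (-0.81, adjusted p = 0.0674), and with TMM on autosomal genes (-0.78, adjusted p = 0.0519). In sin-3 libraries hda-3 was at 41.4 ± 8.30 CPM (0.37, SE 0.22, adjusted p = 0.291). Neither mutant's label was contradicted by its own gene. The reads are counted over whole genes, so they do not show which part of hda-3 the remaining reads cover.

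**Figure D1:**
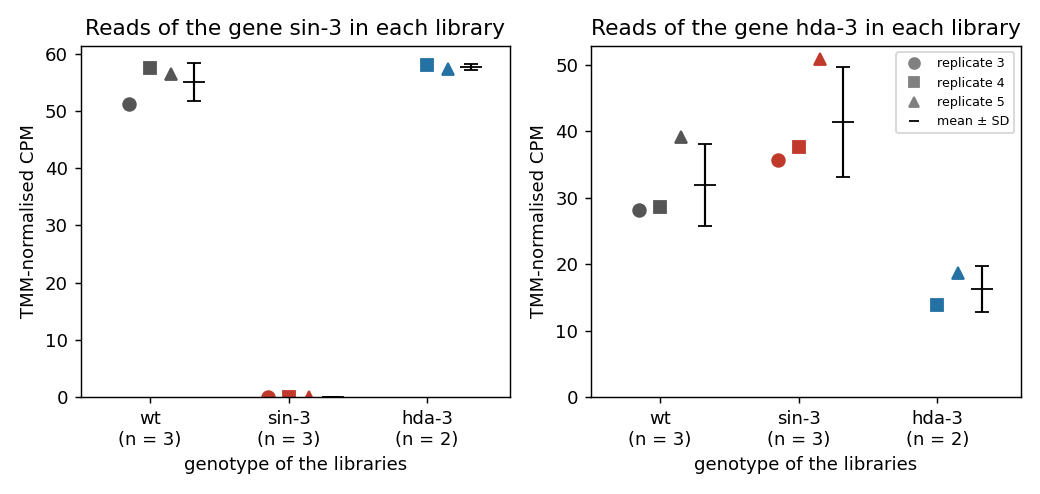
Normalised expression (CPM) of sin-3 and hda-3 in each library, by genotype; each point is 1 library. The sin-3 gene was at 0 to 0.0778 CPM in the sin-3 libraries and above 51 CPM in the others, and hda-3 was at 13.9 and 18.7 CPM in the hda-3 libraries against 28.2 to 39.1 CPM in wt.

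The genes named first for sin-3 gonads had the largest changes among called genes of at least 10 CPM on average whose sin-3 libraries all lay on one side of wt. They were chosen by fold change and not by function. The X-linked gene lin-15B, which encodes a THAP-domain repressor of the synMuv B class, rose from 10.7 ± 2.22 to 33.6 ± 6.18 CPM (log2 1.66, SE 0.22, adjusted p = 0.00242, n = 3 per group). The Argonaute gene vsra-1 rose from 16.9 ± 3.61 to 50.8 ± 2.03 CPM (1.59, SE 0.19, adjusted p = 0.00161), and rict-1, which encodes the Rictor subunit of TORC2, from 24.3 ± 3.30 to 70.02 ± 13.9 CPM (1.53, SE 0.21, adjusted p = 0.00259). In the other direction inx-14, which encodes a germ cell innexin that joins germ cells to the gonadal sheath, fell from 104.2 ± 4.78 to 23.6 ± 3.77 CPM (-2.14, SE 0.19, adjusted p = 2.84e-04). The fucosyltransferase gene fut-3 fell by 2.54 (SE 0.20, adjusted p = 1.85e-04), and apc-10, a subunit gene of the anaphase-promoting complex, fell by 2.08 (SE 0.32, adjusted p = 0.00454).

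Of 10302 genes tested, 783 were called in sin-3 against wt, 276 higher and 507 lower; 2762 had an unadjusted p under 0.05. Further large rises under the same rule were cht-3 (1.92, adjusted p = 0.0305), scpl-3 (1.69), pqn-21 (1.68), fbxb-7 (1.58), spg-20 (1.55), ccg-1 (1.44) and emb-9 (1.41), which encodes a chain of type IV collagen. Further large falls were those of his-60 (-2.72), gcsh-2 (-2.49), cin-4 (-2.41), bpl-1 (-2.33), dhs-12 (-2.14) and his-59 (-2.13). Of the 55 called values of named genes in this comparison, 22 kept their call in every fit without 1 library. Of the genes in this paragraph, cht-3, scpl-3, fbxb-7, ccg-1 and emb-9 did not, with adjusted p up to 0.126, 0.0921, 0.102, 0.148 and 0.115. The rise of scpl-3 was at 1.09 without sin-3 replicate 5. The number of calls depended on single libraries: it was 222, 388 and 209 without wt replicates 3, 4 and 5, 487 and 460 without hda-3 replicates 4 and 5, 200 without sin-3 replicate 4 and 1453 without sin-3 replicate 3. The excess of falls depended on them too. Higher genes were 22.5, 18.3 and 14.8% of the calls without wt replicates 3, 4 and 5, 47.7% without sin-3 replicate 3, and 50.1% (688 higher and 686 lower) without a filter on low counts.

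Among the fixed lists, histone genes were called lower in sin-3. Of 32 measured, 16 were called lower and 0 higher (19 and 0 adjusted over the list alone), with a median of -1.75 (camera adjusted p = 8.32e-12; adjusted p = 0.746 with an estimated correlation). Examples were his-62 (-3.002, SE 0.39), his-6 (-3.67, SE 0.49) and his-32 (-2.90, SE 0.40). Members of this family share reads, so single values are uncertain. As a share of reads outside ribosomal RNA, all 81 histone genes of the list took 1.42 ± 0.448% in sin-3 and 1.99 ± 0.365% in wt (exact permutation p = 0.2, adjusted 0.311). The libraries overlapped in this share, with 1.83% in sin-3 replicate 3 and 1.59% in wt replicate 4. Genes of cytosolic ribosomal proteins had a median of -1.47, with 9 of 81 lower and 1 higher, and 63 lower and 2 higher adjusted over the list alone (camera adjusted p = 4.28e-21; adjusted p = 0.746 with an estimated correlation). Among the lower ones were rpl-39 (-1.51), rpl-25.2 (-1.84) and rpl-41.2 (-1.67), while the X-linked rpl-25.1 was higher (1.39). These 4 calls were lost without any 1 wt library and without sin-3 replicate 4 (adjusted p up to 0.0943, 0.119, 0.0991 and 0.106). As a share of reads outside ribosomal RNA, ribosomal protein genes took 9.37 ± 4.65% in sin-3 and 17.3 ± 1.40% in wt, lower in 3 of 3 libraries (exact permutation p = 0.1, the smallest possible; adjusted 0.311). Lower calls of ribosomal protein genes numbered 75 without sin-3 replicate 3, 40 without sin-3 replicate 5, 2 without either hda-3 replicate, and 0 without sin-3 replicate 4 or any 1 of the wt replicates. For histones the smallest number was 8, without wt replicate 3; without wt replicate 5 or sin-3 replicate 4 it was 9.

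Genes of the meiotic and small RNA machinery were also among the falls. Meiosis genes had 6 of 46 lower and 0 higher (6 and 0 adjusted over the list alone; median -0.11; camera adjusted p = 0.0209; adjusted p = 0.746 with an estimated correlation). The strongest was pch-2, the pachytene checkpoint ATPase gene, which fell from 18.3 ± 0.830 to 4.61 ± 0.664 CPM (-1.99, SE 0.23). It was followed by him-14 (-1.29), which encodes an MSH4 homologue, him-6 (-0.97), which encodes the BLM helicase, and dsb-1 (-0.81), needed for meiotic double-strand breaks. Germ granule and small RNA genes had 7 of 52 lower and 3 higher (9 and 3 adjusted over the list alone; median -0.20; camera adjusted p = 0.0181; adjusted p = 0.746 with an estimated correlation). The piRNA factor gene tofu-2 fell by 1.52 (SE 0.22), hrde-2 by 1.17 and simr-1 by 1.098. The higher ones were meg-3 (1.01), meg-1 (0.81) and meg-2 (1.53), X-linked genes of embryonic P granule proteins; meg-1 and meg-2 were chosen after their values were seen. Both list calls rested on single libraries. The meiosis call was lost without wt replicate 5 (median -0.02, adjusted p = 0.199), sin-3 replicate 4 (-0.05, adjusted p = 0.102) and sin-3 replicate 5 (-0.13, adjusted p = 0.0567). The germ granule call was lost without wt replicate 4 (adjusted p = 0.0623), wt replicate 5 (adjusted p = 0.0692), sin-3 replicate 4 (adjusted p = 0.0731) and sin-3 replicate 5 (adjusted p = 0.0580). Its median was -0.31 without wt replicate 3. Without 1 library the meiosis genes lower numbered 1 to 5 (fewest without sin-3 replicate 4) and the germ granule genes lower 2 to 9 (fewest without sin-3 replicate 4, most without sin-3 replicate 5). Among the named members, pch-2, tofu-2 and simr-1 kept their calls in every such fit. Without sin-3 replicate 4 those of him-14, him-6, dsb-1, hrde-2 and meg-3 were lost (adjusted p = 0.0878, 0.0605, 0.127, 0.0508 and 0.0738), and without wt replicate 5 those of him-14, dsb-1 and meg-3 (adjusted p = 0.0816, 0.12 and 0.111).

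Oogenesis genes had 1 of 31 higher, egg-3 (0.73), and 1 lower, egg-5 (-1.21), which act in the oocyte-to-embryo transition (the same numbers adjusted over the list alone; median -0.31; camera adjusted p = 0.0200; adjusted p = 0.818 with an estimated correlation). That call was lost without wt replicate 4 (median -0.13, adjusted p = 0.262), sin-3 replicate 4 (-0.32, adjusted p = 0.105) and sin-3 replicate 5 (-0.17, adjusted p = 0.411). The median was -0.51 without wt replicate 5 and -0.61 without sin-3 replicate 3, and both gene calls were lost without any 1 wt library and without sin-3 replicate 4 (adjusted p up to 0.131 for egg-3 and 0.124 for egg-5). Cell cycle and DNA replication genes had 0 of 32 called by edgeR (also 0 adjusted over the list alone; 3 higher and 6 lower at an unadjusted p under 0.05; 1 and 2 called by DESeq2, 0 and 4 by voom). The list had a median of -0.32 and a camera adjusted p of 0.0401 (adjusted p = 0.746 with an estimated correlation). The call was lost under RLE factors (adjusted p = 0.0585), TMM on autosomal genes (adjusted p = 0.0534) and without wt replicate 4 (median -0.19, adjusted p = 0.262), sin-3 replicate 4 (adjusted p = 0.162) or sin-3 replicate 5 (adjusted p = 0.0998). Its member closest to the threshold was cdk-1 (-0.78, adjusted p = 0.0623).

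Of the 5 lists of somatic tissue markers, those of intestine, somatic gonad and muscle were called higher in sin-3, and those of neuron (camera adjusted p = 0.578) and epidermis and cuticle (camera adjusted p = 0.125) were not called. Intestine markers had 2 of 30 higher, lys-7 and clec-63 (7 adjusted over the list alone, 0 lower), with a median of 1.44 (camera adjusted p = 7.18e-04; adjusted p = 0.746 with an estimated correlation). The lysozyme gene lys-7 had 2 reads in all of wt, and the ratio was 41.6 (95% interval 11.33 to 346.4). Higher intestine genes numbered 0 without wt replicate 4 or wt replicate 5, 1 without sin-3 replicate 4, sin-3 replicate 5 or either hda-3 library, 6 without wt replicate 3 and 7 without sin-3 replicate 3. Without wt replicate 5, lys-7 had an adjusted p of 0.0771 and clec-63 of 0.152. Without wt replicate 3 both had 0 reads in wt, and taking a floor of 3 counts over the group clec-63 was at least 18.08-fold and lys-7 at least 20.46-fold higher. Somatic gonad markers had 2 of 20 higher (5 adjusted over the list alone, 0 lower), a median of 0.97 and a camera adjusted p of 0.00132 (adjusted p = 0.746 with an estimated correlation). They were nmy-1, an X-linked non-muscle myosin gene that rose from 3.37 ± 1.00 to 14.7 ± 1.87 CPM (2.14, SE 0.31, adjusted p = 0.00307), and the integrin gene ina-1 (1.32). Only nmy-1 kept its call in every fit without 1 library; ina-1 had an adjusted p of 0.15 without wt replicate 5, and 4 somatic gonad genes were higher without sin-3 replicate 3. Muscle markers had 0 of 25 called by edgeR (0 adjusted over the list alone; 8 higher at an unadjusted p under 0.05; 4 by DESeq2 and 3 by voom). The list had a median of 0.91 and a camera adjusted p of 0.00484 (adjusted p = 0.746 with an estimated correlation; adjusted p = 0.0585 without wt replicate 5), and its member closest to the threshold was unc-54 (1.13, adjusted p = 0.0595). The mitochondrially encoded genes had 0 of 12 called by edgeR (0 adjusted over the list alone; 3 higher at an unadjusted p under 0.05; 4 by DESeq2 and 1 by voom). They had a median of 1.364 and a camera adjusted p of 0.00810 (adjusted p = 0.746 with an estimated correlation). This call was lost without wt replicate 3 (median 0.91, adjusted p = 0.112) or sin-3 replicate 3 (1.03, adjusted p = 0.0894), and WBGene00010958 was closest to the threshold (1.67, adjusted p = 0.0662). Their share of reads outside ribosomal RNA was 2.83 ± 1.29% in sin-3 and 0.857 ± 0.664% in wt (exact permutation p = 0.2, adjusted 0.311).

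The other 13 lists were not called in sin-3. Spermatogenesis genes had 0 of 56 higher and 3 lower (the same adjusted over the list alone), with a median of 0.78 (camera adjusted p = 0.402). The 3 were spe-44 (-1.49), a transcription factor gene of sperm formation, cpb-1 (-1.73), a CPEB homologue needed for spermatogenesis, and spe-5 (-1.18). Genes of major sperm proteins, the sperm cytoskeleton proteins, had 0 of 29 called (0 adjusted over the list alone, at an unadjusted p under 0.05, by DESeq2 and by voom). Their median was 0.76 (0.67 with the 3 genes at 0 reads in a group set to their bound), while camera ranked them toward lower values (adjusted p = 0.767). The closest was msp-81 (1.78, adjusted p = 0.209). Without sin-3 replicate 3 both lists were called higher, with medians of 1.15 (adjusted p = 6.32e-04; 12 of the spermatogenesis genes higher) and 1.18 (adjusted p = 2.09e-04; 9 of the msp genes higher). The SIN3 and histone deacetylase genes had a median of 0.07 and a mean of -0.87, with sin-3 itself the only call (camera adjusted p of the list 0.325; 0 higher and 1 lower adjusted over the list alone). Medians and camera adjusted p were -0.04 and 0.800 for germline stem cells (1 of 16 higher, fog-1, 0.84), and -0.03 and 0.918 for chromatin repressors (lin-15B higher, cec-4, -0.96, and arle-14, -0.90, lower of 38; mean 0.09). They were 0.21 and 0.389 for dosage compensation (1 of 10 higher, sdc-1, 1.38), and 0.14 and 0.538 for sex determination (fog-1 and sex-1, 1.39, higher and fem-2, -1.03, lower of 18). Without wt replicate 5 the calls of spe-44, cpb-1, spe-5, fog-1, arle-14, sdc-1 and sex-1 were lost (adjusted p = 0.0561, 0.0975, 0.126, 0.0798, 0.151, 0.101 and 0.116), and without wt replicate 3 those of cec-4 and fem-2 (0.112 and 0.0537).

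Adjusted over the list alone, calls were 1 higher and 1 lower for germline stem cells, 1 and 2 for chromatin repressors, 1 and 0 for dosage compensation, and 3 and 2 for sex determination. They were 1 and 0 for epidermis and cuticle, 2 and 0 for embryonic and neuronal fates, and 0 for the 4 lists with no call below. In these 4, genes at an unadjusted p under 0.05 were 2 higher and 2 lower for apoptosis, 2 and 1 for heat shock, 2 and 6 for the respiratory chain and 2 and 1 for neuron. DESeq2 called 2 and 1, 2 and 0, 2 and 2, and 0, and voom 0 and 3, 1 and 0, 1 and 4, and 0 and 1. The median was 0.14 for apoptosis and DNA damage (0 of 22 called, polq-1 closest at 0.77), 0.43 for heat shock and stress (0 of 25, skn-1 at 0.83), -0.05 for the nuclear-encoded respiratory chain (0 of 39, cyc-2.2 at 3.69) and 0.53 for neuron markers (0 of 13, snb-1 at -0.64). It was 0.31 for epidermis and cuticle (1 of 21 higher, col-179, 2.80) and 0.55 for embryonic and neuronal fate factors (1 of 14 higher, pal-1, 1.12). Camera adjusted p for these 6 lists was 0.113 to 0.800. Without wt replicate 3 the epidermis list was called (median 2.43, adjusted p = 0.00142), and without sin-3 replicate 3 the respiratory chain list was (median -0.36, adjusted p = 8.05e-04). Without wt replicate 5 the calls of col-179 and pal-1 were lost (adjusted p = 0.134 and 0.0822). Under other scalings the medians of the stem cell (0.03, TMM on autosomal genes), chromatin (0.01 under RLE factors, 0.04) and respiratory chain lists (0.006) changed sign; no other list of this comparison did.

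**Figure D2:**
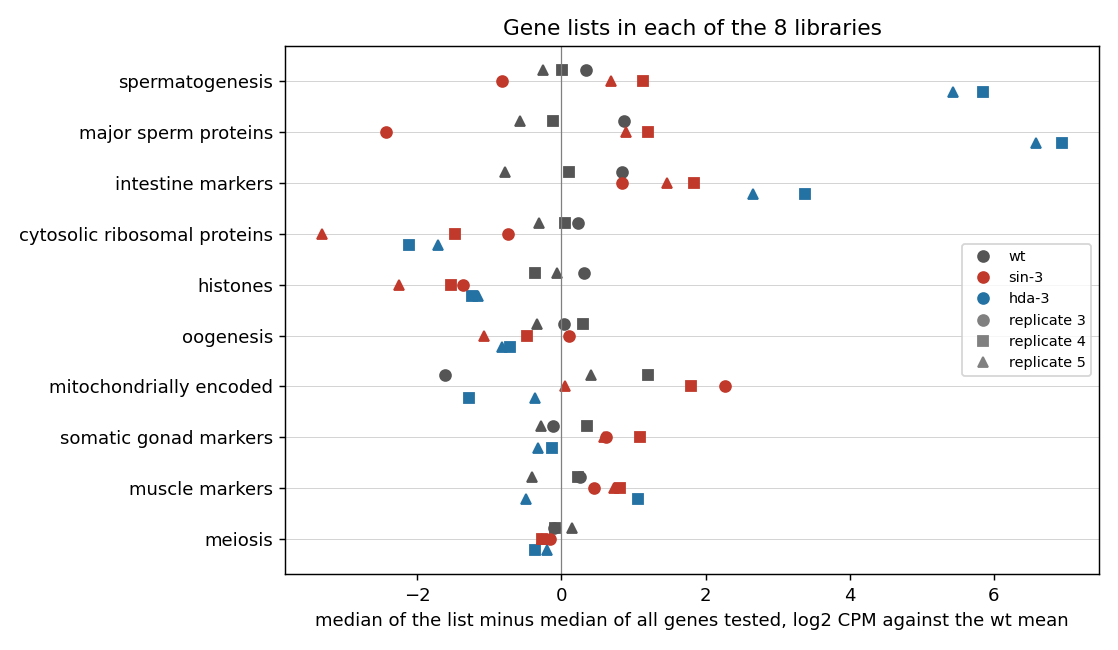
Median log2 expression of the members of 10 fixed gene lists in each library, minus the median of all genes tested and relative to the wt mean; each point is 1 library. In the hda-3 libraries the spermatogenesis and msp lists lie above all other libraries, and in every mutant library the ribosomal protein and histone lists lie below every wt library.

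The germ line of hermaphrodites keeps most of the X chromosome at low expression, and X-linked genes were therefore compared with autosomal genes. In sin-3 gonads, 59 of 1187 X-linked genes rose and 7 fell, whereas 216 of 9099 autosomal genes rose and 500 fell. The median X-linked gene was at 0.70 and the median autosomal gene at 0.05, a difference of 0.65, and 83.1% of X-linked against 52.7% of autosomal genes lay above 0. The medians of chromosomes I to V were between -0.01 and 0.09. Among called X-linked genes of at least 10 CPM on average, with every sin-3 library above every wt library, the largest rises were those of lin-15B, let-2 (1.40), a type IV collagen gene, vha-15 (1.09), a subunit gene of the vacuolar proton pump, meg-3 (1.01) and pqn-65 (0.98). Calls other than that of lin-15B were each lost without wt replicate 3 or wt replicate 5, among others, with adjusted p up to 0.145, 0.152, 0.111 and 0.123.

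The difference between X-linked and other genes in sin-3 had a camera p of 1.06e-11, and p = 0.196 with an estimated correlation of 0.227. Per library, the X minus autosome difference was 0.64 ± 0.26 in sin-3 (0.38, 0.64 and 0.89) and 0.02 ± 0.32 in wt (0.21, 0.21 and -0.35), higher in 3 of 3 libraries (exact permutation p = 0.1, the smallest possible; adjusted 0.311). X-linked genes took 2.29 ± 0.940% of nuclear coding reads in sin-3 and 0.933 ± 0.203% in wt (exact permutation p = 0.1, adjusted 0.311). Against autosomal genes matched on expression and exonic length, a comparison added after the data were seen, the difference was 0.37 (bootstrap SE over genes 0.0408).

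In hda-3 gonads the X minus autosome difference was 0.38 (0.32 against -0.05), and the test did not call it (camera p = 0.346; p = 0.845 with an estimated correlation). Of 1187 X-linked genes 43 rose and 24 fell, against 1345 and 476 of 9099 autosomal genes. By the same rule, with every hda-3 library above every wt library, the largest X-linked rises were those of ilys-5 (4.08), an invertebrate lysozyme gene, lec-8 (3.89), a galectin gene, gpd-2 (1.35), lin-15B (1.14, SE 0.24, adjusted p = 0.0054) and pfk-1.1 (1.12), a phosphofructokinase gene. Without hda-3 replicate 4, lec-8, gpd-2 and pfk-1.1 were not called (adjusted p = 0.559, 0.665 and 0.203), and lec-8 and gpd-2 stood at 1.00 and 0.45. Nor were they called without any 1 wt library (adjusted p = 0.0522 to 0.119), lec-8 without any 1 sin-3 library (adjusted p up to 0.0994), or pfk-1.1 without hda-3 replicate 5 (adjusted p = 0.0639). The call of ilys-5 was kept in every fit without 1 library but lost with the replicate number as a block (3.75, adjusted p = 0.152) and by voom (4.11, adjusted p = 0.0523); over its alternatives the adjusted p was 2.43e-07 to 0.152. The X minus autosome difference depended on single libraries: it was -0.03 without hda-3 replicate 4, 0.15 without wt replicate 5, and 0.59 without hda-3 replicate 5 (camera at the preset correlation, p = 0.0336). It depended on low counts too, with 0 without a filter (camera at the preset correlation, p = 0.775), 0.62 under the stricter filter and 0.48 among the 125 X-linked and 4088 autosomal genes at 10 CPM or more (camera at the preset correlation, p = 5.02e-05 and 2.98e-09). Without a filter, genes with a read in any library were kept, and the median of all genes was exactly 0 too. The difference of 0 there thus says little about X-linked genes. X-linked genes took 1.90 ± 0.647% of nuclear coding reads (exact permutation p = 0.2, the smallest possible; adjusted 0.311), and the difference per library was 0.34 ± 0.40 (exact permutation p = 0.6).

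**Figure D3:**
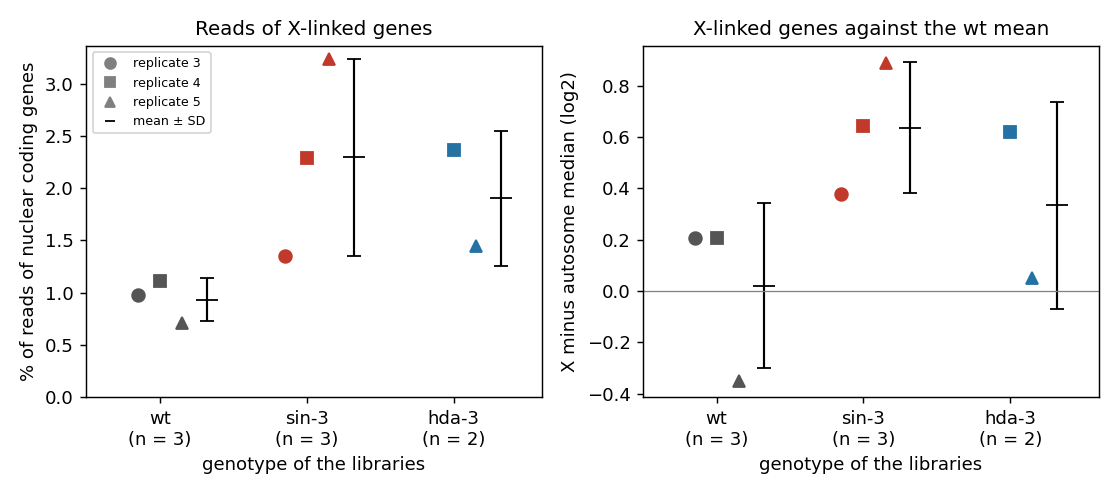
X-linked expression per library, as the percent of nuclear coding reads on X-linked genes and as the median log2 expression of X-linked minus autosomal genes; each point is 1 library. The sin-3 libraries lie at 1.35 to 3.23% and the wt libraries at 0.71 to 1.11%, while the hda-3 libraries lie at 2.36 and 1.45%.

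In hda-3 gonads, most genes of sperm formation rose, and their lists had by far the largest median rises of the fixed lists. The sperm-specific family gene ssp-10 went from 0.452 ± 0.204 CPM in wt (n = 3) to 114 ± 0.948 CPM in hda-3 (n = 2), a log2 fold change of 7.98 (SE 0.38, adjusted p = 1.34e-06). The PP1 phosphatase gene gsp-4, which acts in sperm meiosis and motility, went from 0.591 ± 0.513 to 103 ± 21.6 CPM (7.53, SE 0.91, adjusted p = 8.66e-04). With them rose alg-4 (6.33, SE 0.51) and alg-3 (4.69, SE 0.54), Argonaute genes of spermatogenesis. Of 56 spermatogenesis genes 44 rose and 0 fell (47 and 0 adjusted over the list alone), with a median of 6.03 (5.92 with the gene at 0 reads in a group set to its bound; camera adjusted p = 3.13e-19; adjusted p = 0.743 with an estimated correlation). All 29 msp genes tested rose, also adjusted over the list alone, with a median of 6.82 (6.81 with 2 genes at their bound; camera adjusted p = 1.62e-16; adjusted p = 0.846 with an estimated correlation). In sin-3 libraries the msp genes took 0.0157 ± 0.0131% of reads outside ribosomal RNA, in wt 0.00521 ± 0.00264%, and in hda-3 1.06 ± 0.177% (hda-3 against wt, exact permutation p = 0.2, the smallest possible; adjusted 0.311). Fewest calls were made without hda-3 replicate 5 for spermatogenesis (36) and without hda-3 replicate 4 for msp genes (26).

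Other named genes of this group were msp-38 (8.50, SE 1.29), ssp-16 (8.36), nspd-2 (8.05), ssq-4 (7.98), nsph-3.1 (7.81; 1.099 ± 0.301 to 238 ± 23.8 CPM), gln-2 (7.80), a glutamine synthetase gene, msp-81 (7.77), nsph-2 (7.71), msp-51 (7.64), msp-10 (7.30), ssq-3 (6.89) and msp-77 (6.52). For msp-32, with 0 reads in wt, the level was at least 130.2-fold higher, taking a floor of 3 counts over the group. Only msp-38 among these lost its call without 1 library (hda-3 replicate 4, adjusted p = 0.0549). With the replicate number as a block msp-38 and gln-2 were not called (adjusted p = 0.072 and 0.0612). Reads shared between paralogs were not counted, so the division among msp, nspd, nsph and ssp copies is uncertain. In wt only 5 of the 56 spermatogenesis genes and 0 of the 29 msp genes reached 10 CPM. Most of the genes that rose were therefore low in wt. Among the 5 were spe-44, cpb-1 and spe-5, named above for sin-3, and these did not rise beyond the spread in wt. The gene spe-44 was at 13.75 ± 1.79 CPM in wt and 13.13 ± 1.13 CPM in hda-3. The gene cpb-1 was at 16.05 ± 4.63 and 13.01 ± 0.782 CPM, and spe-5 at 16.14 ± 5.46 and 16.62 ± 1.95 CPM.

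Among called genes of at least 10 CPM on average, with every hda-3 library below every wt library, the 10 largest falls were the following. The vitelline layer genes perm-2 and perm-4 went from 2844 ± 1390 to 153 ± 32.6 CPM (-4.22, SE 0.94, adjusted p = 0.00755) and from 3366 ± 1586 to 193 ± 29.3 CPM (-4.12, SE 0.87, adjusted p = 0.00532). The trypsin-like protease gene try-14 fell by 3.55 (SE 0.62), the sheath innexin gene inx-8 fell by 3.098 (SE 0.60), and tbh-1, the tyramine beta-hydroxylase gene, by 2.85 (SE 0.44). The remaining large falls were sdz-27 (-2.94), his-60 (-2.89), far-2 (-2.78), skpo-1 (-2.76) and arrd-13 (-2.71). Oogenesis genes as a list had 0 of 31 higher and 3 lower, perm-2, perm-4 and egg-5 (-1.23), the same adjusted over the list alone, with a median of -0.82 (camera adjusted p = 6.21e-05; adjusted p = 0.846 with an estimated correlation). Without hda-3 replicate 4 the calls of perm-2, perm-4, inx-8, far-2, skpo-1 and egg-5 were lost (adjusted p = 0.0965, 0.0806, 0.0762, 0.193, 0.263 and 0.199). Without hda-3 replicate 5 the same held for perm-2 (0.0533), inx-8 (0.0607), far-2 (0.169), skpo-1 (0.108) and egg-5 (0.117). The call of egg-5 was also lost without wt replicate 4 (0.108) and sin-3 replicate 4 (0.0808). That of far-2 was lost without wt replicates 3 and 4 and sin-3 replicate 4 (0.0587, 0.0635 and 0.0728), and that of skpo-1 without sin-3 replicates 3 and 4 (0.0524 and 0.0683). try-14, sdz-27, his-60, tbh-1 and arrd-13 kept theirs in every such fit. Oogenesis genes lower numbered 0 and 1 without hda-3 replicates 4 and 5, 2 without wt replicate 4 or sin-3 replicate 4, and 8 without sin-3 replicate 3 or 5. Somatic gonad markers had 3 of 20 lower, inx-8, inx-9 (-2.18) and acy-4 (13.04 times lower on pooled counts, 95% interval 3.146 to 115.4), and 1 higher, nmy-1 (1.16), the same adjusted over the list alone, with a median of -0.31 (camera adjusted p = 0.352). Without hda-3 replicate 4 the calls of inx-9, acy-4 and nmy-1 were lost (adjusted p = 0.065, 0.0952 and 0.232; acy-4 then at 0 reads in hda-3 and at least 3.268-fold lower), and inx-9 was at -1.41 without wt replicate 4.

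Ribosomal protein genes were called lower as a list in hda-3. Of 81, 44 were lower and 1 higher (77 and 2 adjusted over the list alone), with a median of -1.93 (camera adjusted p = 3.98e-16; adjusted p = 0.846 with an estimated correlation). Examples were rpl-37 (-2.297, SE 0.58), rpl-41.2 (-2.04, SE 0.48) and rpl-29 (-1.99, SE 0.46), each lost without hda-3 replicate 4 (adjusted p = 0.134, 0.128 and 0.096). The higher one was rpl-42, at 1 read in all of wt, with a ratio of 110 (95% interval 19.45 to 4374). Their share of reads outside ribosomal RNA was 8.39 ± 1.55% (17.3 ± 1.40% in wt; exact permutation p = 0.2, the smallest possible; adjusted 0.311). The number called lower was 22 under RLE factors and 23 with TMM on autosomal genes. It was 4, 4 and 18 without wt replicates 3, 4 and 5, 0 and 1 without hda-3 replicates 4 and 5, 10 without sin-3 replicate 4, and 75 and 77 without sin-3 replicates 3 and 5. Histones had 9 of 32 lower and 1 higher (12 and 1 adjusted over the list alone), a median of -1.29 and a camera adjusted p of 1.45e-05 (adjusted p = 0.846 with an estimated correlation). his-60 (-2.89), his-6 (-2.14) and his-62 (-1.90) were lower, the latter pair not without hda-3 replicate 4 (adjusted p = 0.106 and 0.102), and his-70 rose, with a ratio of 86.7 (95% interval 29.43 to 422.4). Lower histone calls were 2 and 4 without wt replicates 3 and 5, 1 and 2 without hda-3 replicates 4 and 5, 6 without sin-3 replicate 4 and 14 without sin-3 replicate 5.

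Intestine markers rose in hda-3, in 19 of 30 genes with 1 lower (26 and 1 adjusted over the list alone), with a median of 3.17 (camera adjusted p = 4.12e-07; adjusted p = 0.846 with an estimated correlation). They included the aspartyl protease gene asp-1 (4.18, SE 0.64), the yolk protein gene vit-1 (3.52, SE 0.64) and lys-4 (4.95, SE 0.91); clec-63 (5.18) rose from 0.169 CPM (at 0 reads in wt without wt replicate 3, and then at least 63.98-fold higher), and the lower one was far-2. Levels stayed low: the most abundant in hda-3, vit-2 (chosen after its value was seen), was at 66.5 CPM in hda-3, 23.3 in sin-3 and 8.68 in wt, while far-2 was at 24.2, 254 and 167. The count of rises was 12 and 8 without wt replicate 4 and hda-3 replicate 4. Meiosis genes had 0 of 46 higher and 2 lower, htp-2 (-1.07) and sun-1 (-0.77), with 0 adjusted over the list alone and a median of -0.32 (camera adjusted p = 0.00383; adjusted p = 0.846 with an estimated correlation). That call was lost without hda-3 replicate 4 (-0.23, adjusted p = 0.131), as were those of htp-2 and sun-1 (adjusted p = 0.232 and 0.293), and the median was -0.16 and -0.14 without sin-3 replicates 4 and 5. The nuclear-encoded respiratory chain had 2 of 39 lower, cox-7C (-1.46) and cyc-2.1 (-1.32), and 1 higher, cyc-2.2 (8.30), a cytochrome c gene, the same adjusted over the list alone, with a median of -0.58 (camera adjusted p = 0.00383; adjusted p = 0.846 with an estimated correlation). Its lower genes numbered 10 and 11 without sin-3 replicates 3 and 5, and 0 without wt replicate 3 or either hda-3 library; cox-7C and cyc-2.1 had adjusted p of 0.103 and 0.252 without hda-3 replicate 4.

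The other 15 lists were not called in hda-3, somatic gonad markers among them. Germ granule and small RNA genes had 3 of 52 higher and 6 lower (3 and 5 adjusted over the list alone; median -0.25, camera adjusted p = 0.0804). alg-3, alg-4 and meg-3 (chosen after its value was seen) were higher, and tofu-2 (-1.32) and pid-1 (-1.37) were among the lower. The list was called without wt replicate 3 (adjusted p = 0.0121) and hda-3 replicate 5 (adjusted p = 0.0105), and without hda-3 replicate 4 the calls of tofu-2 and pid-1 were lost (adjusted p = 0.0581 and 0.091). Germline stem cell genes had fog-3 (2.97), a gene of sperm fate, higher and gld-1 (-0.71) lower of 16 (median -0.07), and sex determination genes had fog-3 higher and gld-1 and fog-2 (-0.79) lower of 18 (median 0.03). lin-15B was the 1 call of 38 chromatin genes (median 0.13, while camera ranked them lower), hda-3 that of the SIN3 and deacetylase genes (-0.02), ctl-2 (3.96) that of 25 heat shock genes (-0.05), and unc-22 (-2.40) that of 25 muscle markers (0.44). Further single calls were col-179 (2.51) among 21 epidermis markers (0.94) and elt-1 (2.14) among 14 embryonic and neuronal fate genes (0.77; 2 higher under the stricter filter, adjusted p = 0.0458). The lists with 0 calls by edgeR were dosage compensation (median 0.20; dpy-27 at 0.94), cell cycle (-0.32; hcp-3 at -0.68), apoptosis (-0.002; chk-1 at -0.58), mitochondrially encoded (-1.14, camera adjusted p = 0.141; WBGene00000829 at -2.03) and neuron (-0.46, mean 0.05; snb-1 at -0.64). In that order, genes lower at an unadjusted p under 0.05 were 0, 5, 1, 1 and 1, with 1 higher for neuron, and DESeq2 called 0, 0, 0, 1 lower and 1 higher. Voom called 1 higher for dosage compensation, 9 lower for cell cycle, 1 lower for apoptosis, 0 for mitochondrially encoded, and 2 higher and 1 lower for neuron. Camera adjusted p of the lists not given above was 0.106 to 0.905.

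Adjusted over the list alone, calls in these lists were 1 higher for germline stem cells, 2 higher and 3 lower for sex determination, 1 higher for chromatin genes, 1 lower for the SIN3 and deacetylase genes, and 0 for the others apart from the germ granule and somatic gonad lists. Single libraries moved some of them across the threshold. Without wt replicate 3 the mitochondrially encoded (-1.59, adjusted p = 2.49e-04) and epidermis lists (2.84, adjusted p = 0.0121) were called. So were, without wt replicate 5, the cell cycle list (-0.43, adjusted p = 0.0351), and without hda-3 replicate 5 the mitochondrially encoded list (-1.72, adjusted p = 0.0350). Muscle markers were called lower without hda-3 replicate 4 (-0.54, adjusted p = 0.0252) and higher without hda-3 replicate 5 (0.92, adjusted p = 0.0208). Of the named calls in the other lists, fog-3 and lin-15B kept theirs in every fit without 1 library. The calls of gld-1, fog-2, ctl-2, unc-22, col-179 and elt-1 were lost without hda-3 replicate 4 (adjusted p = 0.376, 0.310, 0.635, 0.327, 0.394 and 0.112), where ctl-2 stood at 1.58 and col-179 at 1.33. Under RLE factors and TMM on autosomal genes the medians of the SIN3 and deacetylase (0.12 and 0.17), stem cell (0.07 and 0.12), apoptosis (0.14 and 0.18) and heat shock lists (0.10 and 0.15) were above 0.

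In all, 1888 genes were called in hda-3 against wt, 1388 higher and 500 lower (73.5% higher); 3320 had an unadjusted p under 0.05. The split depended on the scaling: it was 1469 and 238 under RLE factors (86.1% higher) and 1499 and 209 with TMM on autosomal genes (87.8%). Those scalings moved the median of all genes from -0.02 to 0.12 and 0.17. By voom it was 1712 and 1321 (56.4%). Without hda-3 replicate 4 there were 1048 calls, 995 higher and 53 lower. The lower genes numbered 85 without hda-3 replicate 5, 187, 287 and 259 without wt replicates 3, 4 and 5, 155 without sin-3 replicate 4 and 805 without sin-3 replicate 5. Of the 62 called values of named genes in this comparison, 31 kept their call in every fit without 1 library.

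The difference between the mutants was tested directly. Sperm genes were among those lower in sin-3 than in hda-3: ssp-10 was at 0.963 ± 0.457 CPM in sin-3 and 114 ± 0.948 CPM in hda-3 (-6.74, SE 0.34, adjusted p = 1.25e-06), msp-65 at -7.38 (SE 0.87) and msp-152 at -6.74 (SE 0.67). In the other direction tbh-1 was at 59.5 ± 18.96 CPM in sin-3 and 3.70 ± 1.09 CPM in hda-3 (4.02, SE 0.47, adjusted p = 2.12e-04), and ccg-1 at 26.5 ± 11.6 and 1.66 ± 0.330 CPM (4.00, SE 0.50). There were 1575 calls, 267 higher and 1308 lower in sin-3, with 2568 at an unadjusted p under 0.05. The higher genes numbered 89 and 88 without hda-3 replicates 4 and 5, 110 and 524 without sin-3 replicates 4 and 5, and 968 by voom. Of 56 spermatogenesis genes 48 were lower in sin-3 than in hda-3 (50 adjusted over the list alone; median -5.01; camera adjusted p = 2.48e-22; adjusted p = 0.570 with an estimated correlation). By the same measure all 29 msp genes were lower, also over the list alone (-6.06, or -6.02 with 2 genes at their bound; camera adjusted p = 1.47e-19; adjusted p = 0.615 with an estimated correlation). Somatic gonad markers had 6 of 20 higher in sin-3 (8 adjusted over the list alone; median 1.30; camera adjusted p = 3.00e-05; adjusted p = 0.615 with an estimated correlation). Without hda-3 replicate 4 or 5 that number was 1, without sin-3 replicate 4 it was 2, and without wt replicate 4 or sin-3 replicate 5 it was 4.

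The X minus autosome difference between the mutants was 0.30 (camera p = 7.79e-07; p = 0.328 with an estimated correlation). Without 1 library it was 0.75 (hda-3 replicate 4), 0.13 (hda-3 replicate 5), 0.46 (sin-3 replicate 3) and 0.19 (sin-3 replicate 5). It was not called among genes at 10 CPM or more (0.01; camera at the preset correlation, p = 0.112). The list of mitochondrially encoded genes was called higher in sin-3 by camera, with 2 of 12 genes called (WBGene00010958 and WBGene00010965, the latter chosen after its value was seen; 10 adjusted over the list alone; median 2.58; camera adjusted p = 1.13e-04; adjusted p = 0.940 with an estimated correlation). The number was 11 without wt replicate 3, 4 without wt replicate 4 and 0 without hda-3 replicate 4. The list of intestine markers was called lower (4 of 30 lower, elt-7, asp-1, cpr-4 and lys-1, and 1 higher, far-2, elt-7, cpr-4 and lys-1 chosen after their values were seen; 8 and 1 adjusted over the list alone; median -1.58; camera adjusted p = 0.00235; adjusted p = 0.940 with an estimated correlation), a call lost without hda-3 replicate 4 (-1.06, adjusted p = 0.0762). Of these genes 1 was lower without hda-3 replicate 4 or sin-3 replicate 4 and 7 without hda-3 replicate 5 or sin-3 replicate 5. Oogenesis genes had a median of 0.36 (perm-2 at 4.14 and perm-4 at 3.96, both higher also over the list alone; camera adjusted p = 0.0170; adjusted p = 0.940 with an estimated correlation). That call was lost without sin-3 replicate 3 (0.10, adjusted p = 0.307) and hda-3 replicate 4 (adjusted p = 0.0762). Muscle markers had a median of 0.36 (unc-22 higher, 0 over the list alone; camera adjusted p = 0.0202; adjusted p = 0.940 with an estimated correlation). The median was -0.09 (adjusted p = 0.961) without hda-3 replicate 5, 1.33 without hda-3 replicate 4, and 0.20 and 0.18 without sin-3 replicates 4 and 5. The calls of perm-2, perm-4 and msp-38 (-7.12) were lost without either hda-3 replicate, with adjusted p of 0.102, 0.0912 and 0.0668 without replicate 4 and 0.0656, 0.0641 and 0.0573 without replicate 5. The remaining named gene, ule-5, was higher in sin-3 with a ratio of 1026 (95% interval 283.9 to 8479) but varied widely in sin-3 (29.2 ± 30.7 CPM). It lost its call in 5 of 8 fits without 1 library (adjusted p up to 0.381, without hda-3 replicate 4). Of the other 16 lists none was called between the mutants by camera.

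Both mutants called 80 genes higher, lin-15B, vsra-1, spg-20 and nmy-1 among them, where independent lists would share 37.2, and 35.1% of the 507 genes lower in sin-3 were also lower in hda-3, fut-3, inx-14, tofu-2 and his-60 among them. Independent lists would share 24.6 genes in that direction. Simulated unchanged groups against the same wt libraries shared 0.05 on average in each direction, among 8299 genes tested on average. That is chance with no effect in either mutant, so it does not show whether the effects are shared. Fisher's exact test, given as a description since both comparisons use the same controls, had p = 9.96e-12 and 5.28e-113. The 4 genes called in opposite directions, chosen after their values were seen, were ccg-1, emb-9, ost-1 and lec-5. The covariance of the log2 fold changes across all 10302 genes was 1.69, and over the genes of the simulated sets 0.497 on average, against 0.137 in those sets. The correlation across genes, which are not independent replicates, was 0.589 over all genes, but over the genes of the simulated sets it was 0.453, against 0.478 in those sets, and so not higher. The covariance lay above that of every simulated set (at most 0.149), so shared controls as simulated do not account for all of it. Those sets held no shifts common to many genes of a library. The correlation did not lie above its simulated mean, and the 3 wt libraries were not split between the comparisons. Whether the effects are shared therefore stays open. The numbers depended on single libraries: the higher set held 27, 20 and 6 genes without wt replicates 3, 4 and 5, 18 and 40 without hda-3 replicates 4 and 5, 324 without sin-3 replicate 3 and 23 without sin-3 replicate 4. The lower set held 42, 53, 17, 24, 399 and 32 without wt replicates 3 and 5, hda-3 replicates 4 and 5 and sin-3 replicates 3 and 4, and it held 94 under RLE factors and 84 with TMM on autosomal genes.

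The authors' deposited table for sin-3 called 1112 genes at an adjusted p under 0.05, 427 higher and 685 lower, and their deposited table for hda-3 called 1832, 1313 higher and 519 lower. Of these, 683 and 1457 were also called here, all with the same sign. X-linked genes in the authors' deposited tables were 114 higher and 8 lower in sin-3 and 76 higher and 22 lower in hda-3. Across genes, which are not independent replicates, the log2 fold changes of the authors' deposited tables and of the fit here correlated at 0.973 and 0.979.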

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

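Of the tests in this part, those on the sperm genes of hda-3, the one on somatic RNA in sin-3 and the matched X comparison between the mutants were chosen after the result was seen. The matched X comparisons of sin-3 and of hda-3 with wt were also added after the data were seen. The results named here, apart from the ribosomal protein genes and the splits of the libraries, were singled out because the mutants differed from each other in the direct test between them.

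The first pattern is that of the sperm genes, most of which rose in hda-3. The median difference of sin-3 from hda-3 was -5.01 for the spermatogenesis list and -6.06 for the msp list, with ssp-10 at -6.745, msp-65 at -7.38, msp-38 at -7.12 and msp-152 at -6.74. If reads shared among msp copies were the cause, spermatogenesis genes outside that family should not have risen in hda-3, but 78.6% of them did. Such reads therefore cannot account for the rise outside the msp family. Reads shared within other families of near-identical copies on the list, such as nspd and ssp, were not tested. Spermatocytes or sperm in the hda-3 tissue, whether from the genotype or from the dissection, stay open: 85.9% of the genes of both lists rose, but that share is the pattern itself and decides nothing. If the hda-3 tissue held fewer late oocytes, the oogenesis list should fall and keep its call with an estimated correlation. Its median was -0.82 and the call was not kept. However, no list was called in hda-3 with an estimated correlation. Even the msp list, with all 29 genes higher, was not (camera adjusted p = 0.846). That requirement could hardly be met by any list, so this test cannot tell. No test here separates sperm genes expressed out of place from more spermatogenic cells in the tissue.

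The second pattern is the X chromosome, where the mutants differed by 0.30 (camera at the preset correlation, p = 7.79e-07, and p = 0.328 with an estimated correlation). Among genes at 10 CPM or more it was 0.01 (camera at the preset correlation, p = 0.112). The test ranked X-linked against autosomal genes, and 14.3% of autosomal but 0.253% of X-linked genes were called lower in sin-3 than in hda-3. It therefore does not separate a rise of the X from that autosomal change. Without the genes of the sperm and somatic lists the difference was 0.30, but 1159 of 1187 X-linked and 8933 of 9099 autosomal genes remained. Leaving out so few genes could hardly move a median. This value therefore says nothing about the 1305 autosomal genes called lower. Low expression and length of X-linked genes might produce such a shift, so X-linked genes were compared with matched autosomal genes, with the bounds that below 0.2 the explanation holds and that at 0.3 or more by over 2 SE it does not. In sin-3 the difference was 0.371 (bootstrap SE 0.0408), between the bounds. In hda-3 it was 0.168 (SE 0.0480), under the lower bound by less than 1 SE and above 0 by over 2 SE. Neither can tell: expression for the matching was averaged over all libraries, mutants included. Autosomal genes that rose in hda-3 (1345 of 9099) were thus matched at a raised level. Among genes at 10 CPM or more the unmatched difference was 0.57 in sin-3 and 0.48 in hda-3 (camera at the preset correlation, p = 8.07e-13 and 2.98e-09). The difference was therefore not confined to genes of low expression. The bins were not fixed in advance: wider bins, run first, gave 0.397 (SE 0.0417) and 0.197 (SE 0.0428). By these the sin-3 value passes the upper bound, so its place depends on the bin width. Passing it would not exclude the explanation, since these SEs are over genes and hold no spread between libraries. The difference per library had an SD of 0.26 in sin-3, 0.40 in hda-3 and 0.32 in wt. For the difference between the mutants itself the matched value was 0.279 (SE 0.0390; 0.284 with wider bins), which lies between the bounds and cannot tell. All 5 of the 5 somatic lists had medians above the autosomal genes in sin-3, but camera did not call those of neuron and epidermis. Other lists lay on both sides, with spermatogenesis (0.78) and heat shock (0.43) above and meiosis (-0.11) below. In hda-3, where the X difference was 0.38, the intestine median was 3.17. Those of neuron (-0.46) and somatic gonad (-0.31) were below 0 there. RNA of somatic tissue, where X-linked genes are expressed, could contribute, but this test does not single it out.

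The third pattern is the lower ribosomal protein genes. As a list they were called in both mutants against wt, but not with an estimated correlation (camera adjusted p = 0.746 in sin-3 and 0.846 in hda-3). They were not called between the mutants (median 0.44, camera adjusted p = 0.204). Short length and high expression might make them sensitive to differences in amplification, so they were compared with matched genes, with the bounds that above -0.3 the explanation holds and that at -0.5 or less by over 2 SE it does not. The differences were -0.70 (SE 0.149) in sin-3 and -0.55 (SE 0.124) in hda-3, and neither can tell. Matching covered 72 of the 81 genes, and it removed part of the fall in both mutants. No biological explanation was tested beyond the genotype itself.

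As a further check, the wt and sin-3 libraries were split in all 10 ways into 3 and 3. Only 1 of 10 splits, the real one, gave as many as 783 genes, and the highest other gave 49. With 10 splits this cannot reach a share under 0.05, so the test cannot tell.

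The other results that differed between the mutants were the following. The number of genes that differed was 1575. The median difference was 2.58 for the mitochondrially encoded list, 1.30 for somatic gonad markers, -1.58 for intestine markers, 0.36 for oogenesis (0.361) and 0.36 for muscle markers (0.363). None of these lists kept its call with an estimated correlation (camera adjusted p = 0.615 to 0.940). Single genes were ule-5 at 9.58, perm-2 at 4.14, tbh-1 at 4.015, ccg-1 at 4.00 (4.001), perm-4 at 3.96 and sin-3 itself at -10.51.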

How the results depend on the processing

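Over all alternatives, 2027 gene values and 1207 list values kept their direction and side of the threshold, 332 and 78 became weaker, 44 and 23 stronger, and 3 list values reversed while no gene value did. Genes called in sin-3 numbered 783, with 1374 without a filter, 1302 by DESeq2 and 1456 by voom, and 200 to 1453 without 1 library (fewest without sin-3 replicate 4, most without sin-3 replicate 3). In hda-3 they numbered 1888, with 1031 under the stricter filter, which tests fewer genes, 3033 by voom, and 1048 to 2672 without 1 library. Between the mutants they numbered 1575, with 973 under the stricter filter, 2675 by voom, and 1091 to 2198 without 1 library. With at least 2-fold change the counts were 572, 1718 and 1497. The X minus autosome difference in sin-3 kept its value of 0.65 but not its call with an estimated correlation, was 0.37 against matched genes, and 0.45 to 0.79 without 1 library. In hda-3 it was 0 and not called without a filter, where the median of all genes was 0 too. It was called under the stricter filter (0.62) and at 10 CPM or more (0.48), and was -0.0341 to 0.59 without 1 library. Between the mutants it was 0.30 with the call lost at an estimated correlation, 0.0101 at 10 CPM or more, and 0.13 to 0.75 without 1 library. By fry, the SIN3 and histone deacetylase list was called in sin-3 and between the mutants. Camera called it in neither, and it holds sin-3 itself. Lists called in sin-3 numbered 10, with 6 under the stricter filter, 0 with an estimated correlation, 2 by fry (that list and histones) and 6 to 12 without 1 library. In hda-3 there were 8, with 0, 3 by fry and 8 to 11, and between the mutants 7, with 0, 3 by fry and 5 to 9. The lists whose direction reversed were msp in sin-3 without sin-3 replicate 3 (1.18; 0.36 to 1.40 without 1 library), where the direction given by camera turned while the median stayed above 0, muscle in hda-3 without hda-3 replicate 4 (-0.54; up to 0.92) and muscle between the mutants without hda-3 replicate 5 (-0.0908; up to 1.33). Genes higher in both mutants numbered 316 without a filter, 218 by DESeq2, 161 by voom and 6 to 324 without 1 library. Genes lower in both numbered 94 under RLE factors, 84 with TMM on autosomal genes, 286 without a filter, 110 under the stricter filter, 503 by voom, 113 with only the groups compared, and 17 to 399 without 1 library. Except where fewer genes or libraries were tested, the cause was not tested.

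Replicate numbers 3 to 5 recur in the groups, but libraries with the same number did not deviate together (correlations of deviations -0.09, 0.05 and 0.11 between sin-3 and wt, and 0.08 and 0.29 between hda-3 and wt), so the numbers were not taken to pair samples. With the number as a replicate block the counts were 989, 1353 and 1351, and 22 values of named genes lost their call. Of the same values, calls were lost for 2 by DESeq2, 7 by voom or RLE factors, and 11 without a filter or with TMM on autosomal genes. Without hda-3 replicate 4 it was 45, without wt replicate 5 43 and without sin-3 replicate 4 42.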

Other observations

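None of the genes in this part was weighed against a technical explanation, and they were chosen after their values were seen. Of the genes called in both mutants against wt, 4 were called in opposite directions: ccg-1, emb-9, a type IV collagen gene, ost-1, the SPARC gene, and lec-5, a galectin gene. Each was higher in sin-3 and lower in hda-3. Because the genes were chosen for this, a large direct difference follows from the choice. Its p-value and its stability add no support. For ccg-1 the log2 fold change was 1.44 in sin-3 (SE 0.38, adjusted p = 0.0417) and -2.56 in hda-3 (SE 0.47, adjusted p = 0.00223), a direct difference of 4.00 (SE 0.50, adjusted p = 2.32e-04). The gene ost-1 was at 17.3 ± 5.97 CPM in wt (n = 3), 44.2 ± 10.5 CPM in sin-3 (n = 3) and 6.90 ± 1.74 CPM in hda-3 (n = 2). Its log2 fold change was 1.35 in sin-3 (SE 0.29, adjusted p = 0.0197) and -1.32 in hda-3 (SE 0.34, adjusted p = 0.0167), and the direct difference was 2.67 (SE 0.35, adjusted p = 3.06e-04). The gene emb-9 was at 1.41 in sin-3 (SE 0.33, adjusted p = 0.0279) and -1.27 in hda-3 (SE 0.38, adjusted p = 0.0382), a difference of 2.68 (SE 0.40, adjusted p = 5.96e-04). The gene lec-5 was at 1.68 in sin-3 (SE 0.46, adjusted p = 0.0467) and -2.49 in hda-3 (SE 0.58, adjusted p = 0.00994), a difference of 4.18 (SE 0.61, adjusted p = 5.34e-04).

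Most calls of these genes against wt rested on single libraries. Those in sin-3 were lost for each gene without wt replicate 3 or 5 or sin-3 replicate 4 (adjusted p up to 0.148 for ccg-1, 0.115 for emb-9, 0.0857 for ost-1 and 0.166 for lec-5). For ccg-1 and lec-5 they were also lost without wt replicate 4, sin-3 replicate 3 or either hda-3 library. Those in hda-3 were lost for ost-1 without wt replicates 4 and 5 and hda-3 replicate 5 (adjusted p up to 0.138), for emb-9 without these, hda-3 replicate 4 and sin-3 replicate 4 (up to 0.183), and for lec-5 without hda-3 replicate 4 (0.119). That of ccg-1 in hda-3, and the direct differences of ccg-1, emb-9, ost-1 and lec-5, were called in every fit without 1 library.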
